A study of Oryza sativa with 4 samples.

How the data were processed

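The series holds 4 rice arrays of the 2-colour Agilent type, read here from 1 scanner file per array and from the table of values that accompanies the series. Per the labels, RNA came from branching panicles of TP309 plants carrying an RFL antisense or an RFL dsRNAi construct and from wild type panicles, was extracted with Tri Reagent, cleaned on RNeasy columns, checked on a Bioanalyzer and labelled with Cy3 or Cy5 as cRNA after T7 amplification. Each array carries transgenic RNA in one dye and wild type RNA in the other, and samples were grouped by construct (n = 2 arrays each). Replicate numbers follow the order of the samples, and in both constructs 1 has the transgenic RNA in Cy5 and 2 in Cy3. The labelling text of the arrays with exchanged dyes names the other dye than their label fields do. The label fields were followed, since arrays of opposite dye orientation then gave like log ratios (r = 0.933 and 0.832 across probes within constructs).

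Spot intensities of both channels were, per the file headers, extracted by the authors with Agilent Feature Extraction, version 8.1.1.1 for the antisense and 9.1.3.1 for the dsRNAi arrays. The log10 ratio of red over green in the same files was, per the file headers, background-corrected and dye-normalized by that software as deposited. The series table holds deposited log2 ratios whose processing is not given in the sources used here. Set against the scanner ratio, its columns correlated at 0.959, 0.975, 0.839 and 0.852 (antisense replicates 1 and 2, dsRNAi replicates 1 and 2), which gave their scale (log2) and direction (Cy5 over Cy3). Their centring stays unknown. Turned to transgenic over wild type, their medians were -0.0046, -0.0366, 0.0842 and 0.0521.

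Probes are named as the scanner files name them, by the accession of a rice cDNA with a description. Of 21495 probes that are not controls, 8549 had a described product and 5565 were described as an unknown expressed protein. Over all 21495, 1905 were described as rice. Other descriptions name the nearest homologue, often from another species, and are given as such. Of the accessions, 0 were found in the reference table of rice genes, so the names of the files were kept. Each probe has its own accession. The RFL-linked, floral MADS-box, flowering time and panicle branching lists were fixed by gene symbol. In them a gene with several probes is represented by the one with the highest mean intensity, with the others given where they differ. The other lists were found by description, and each cDNA counts as a member. The genes counted in those lists are thus cDNAs, and several cDNAs of the same gene count apart.

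Mean foreground and median background signals were corrected with limma's normexp (offset 50) and normalized by loess within each array, with control spots at weight 0 and then left out, and outlier spots (between 1 and 67 per array) left out. Probes well above background in at least 1 channel on at least 2 arrays were kept (18096, of which 17997 had values on enough arrays to be tested). Log2 ratios were turned to transgenic over wild type. Limma (version 3.58.1, R 4.3.3) fitted 1 coefficient per construct to all 4 arrays, with eBayes and Benjamini-Hochberg adjustment at 0.05. The contrasts were the mean of both constructs, each construct alone, dsRNAi minus antisense, and, with a dye term, dye orientation. SE are limma's moderated SE. A probe not well above background on every array of a group has a bound there, from mean log2 values per channel after loess and Aquantile, over the higher of the dimmest signal well above background and its own. Other software was Python 3.11.15, pandas 2.3.3, numpy 2.4.6, matplotlib 3.10.9 and statmod 1.5.0.

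Before the data were examined, these lists were fixed: RFL-linked genes, floral MADS-box, flowering time, panicle branching and meristem, auxin, cytokinin, gibberellin, strigolactone and tillering, cell cycle and histones, ribosomal proteins, small RNA machinery, heat shock and stress, and as markers of other tissues or stages photosynthesis, anther and pollen, secondary wall and lignin, and seed storage. A further 8 lists were written after the largest changes were seen: all MADS-box genes, KNOX, FT and TFL1 family, NAC, fermentation, senescence, starch and sugar, and ethylene. Shifts were tested with limma's camera (preset correlation 0.01, adjusted over the lists of each kind), with an estimated correlation and with fry beside it. With an estimated correlation camera rests on the few residual degrees of freedom of the 4 arrays. Its p can thus rise even where the estimate lies below the preset. For floral MADS-box genes in the mean of both constructs the estimate was -0.036, and the unadjusted camera p rose from 0.00073 to 0.071. A call lost in this way is not in itself a sign of correlated genes. For other lists called at the preset in the mean or the difference, the estimate was often higher. It was 0.853 for panicle branching, 0.534 for KNOX, 0.276 for ribosomal protein, 0.136 for photosynthesis and 0.114 for fermentation genes. All MADS-box and NAC genes had 0.053 and 0.041, and heat shock and senescence genes 0.0103 and -0.0128. Where the estimate lay above the preset, camera p at the preset may be too small. The named genes were chosen by a rule fixed beforehand. It took the 10 largest rises and falls of described cDNAs past 0.05 with 1 sign on all 4 arrays, up to 4 passing members of each list with the largest change (or 2 members as values), and the 5 largest in each direction for each construct and for their difference. It also took the RFL-linked genes. The names of a few of the genes so chosen, and most of their values, are not reported here.

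To find in which samples the constructs' ratios differed, each channel was also fitted apart with limma's separate channel analysis after Aquantile (within-spot correlation 0.245), a test added after the data were examined. Similarity of the constructs was set beside 20 simulations of unchanged groups, with each control shared by an antisense and a dsRNAi array. Alternatives were no background correction, offset 10, the deposited log ratio, the series table, median centring, scaling between arrays, no or a stricter filter, outlier spots kept, a dye term, averaged pairs, construct as random block, an intensity trend, each array left out, mean over a gene's probes, and 1 log2 unit on all 4 arrays. Scan day and software version coincide with construct, and each array is its own slide, so no batch term was fitted.

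The code was tested on simulated data with 200 of 17997 probes changed. In the real data 7508 passed in the mean of both constructs and 2962 in the difference. With so many the Benjamini-Hochberg cutoff is looser, so the shares recovered in the simulations do not give the recovery of small changes in the real data. With variances from the fitted prior, 0%, 98.0% and 100% of changes of 0.5, 1 and 2 log2 units were recovered in the mean of both constructs, with false calls at 4.39% and 4.31% of calls for the larger sizes. In the difference between constructs 0%, 0% and 98.5% were recovered, with false calls at 7.51% for the largest size. With each probe's own variance estimate the recovered shares were 89.0%, 100% and 100%, and 0%, 89.5% and 100%, with false calls between 6.10% and 11.9% of calls wherever any were made. Of 20 simulated lists the 1 shifted by 0.3 was called (adjusted p = 3.48e-31) and 0 others. Noise there was independent between probes, so false calls among correlated genes were not tested. In the separate channel fit, shifts of 0.5, 1 and 2 in the wild type channels were recovered at 30.5%, 100% and 100%, with at most 7 false calls, and gave 0 calls in the transgenic channels.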

Results

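Transgenic rice panicles carrying constructs meant to lower RFL were compared with wild type panicles on 4 arrays, each carrying transgenic RNA in one dye and wild type RNA in the other. RFL is the rice counterpart of LEAFY, a plant transcription factor that controls floral meristem identity. In 2 arrays the transgenic panicles carried an antisense construct, and in the other 2 a double-stranded RNA interference (dsRNAi) construct. Each construct had 1 array with the transgenic RNA in Cy5 and 1 with it in Cy3. The panicles were at the branching stage, from the japonica cultivar TP309. Of 21495 probes on each array, between 16106 and 18191 were well above background in the transgenic channel and between 14722 and 17270 in the wild type channel. After the filter on dim probes, 17997 could be tested. The submitters describe the RNA pools as independent, but the labels do not settle this for the antisense pair. The p-values and SE measure the spread between the arrays of each construct, which may be technical. Disagreement between the constructs does not enter them, so a small SE does not mean that all 4 arrays gave like values. For example, OsMT-1 (AK103162) is given below as 4.81 ± 0.09. Its arrays gave 6.43 and 6.86 with antisense and 3.00 and 2.97 with dsRNAi. The number of arrays limits the precision. Values are log2 ratios of transgenic over wild type, given as mean ± SE over n = 4 arrays unless stated, with limma's Benjamini-Hochberg adjusted p.

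The first question was the level of the targeted gene and of genes linked to RFL in the regulation of flowering and panicle form. No probe name or description on the array names RFL (0 of 21495), so its own level was not analysed here. Among the genes fixed as RFL-linked, 4 had a tested probe. OsMADS18 (AK064704), a MADS-box gene of the group that acts in the switch to flowering, rose by 0.34 ± 0.10 (adjusted p = 0.0278) in the mean of both constructs. It stood at -0.17 with antisense (adjusted p = 0.395) and rose by 0.86 with dsRNAi (adjusted p = 0.00392). OsMADS14 (AK061899), of the same group, fell by 0.27 ± 0.08 in the mean (adjusted p = 0.0353), with -0.63 in antisense (adjusted p = 0.00415) and 0.10 in dsRNAi (adjusted p = 0.586). For both genes the difference between constructs passed (adjusted p = 0.0124 and 0.0222). It lay mainly in the wild type samples. In limma's separate channel fit, dsRNAi minus antisense was -0.88 for each in the wild type channels (adjusted p = 0.00276 and 0.000525). In the transgenic channels it was 0.15 and -0.15 (adjusted p = 0.725 and 0.618). Hd3a (AK072979), which encodes the rice florigen, stood at 0.086 ± 0.10 (adjusted p = 0.532). Over all probes 1 of the 4 rose and 1 fell, and the same counts held adjusted over the list alone. The list had a median of -0.021 and a mean of 0.0092, of opposite sign (camera adjusted p = 0.989, downward). Second probes differed for Hd3a, where AK100491 gave 0.48 ± 0.08 (adjusted p = 0.00273) and AK073219 gave 0.011 ± 0.10 (adjusted p = 0.943), while for OsMADS14 AK069331 gave -0.74 ± 0.16 (adjusted p = 0.00712). Without antisense replicate 1, dsRNAi replicate 1 or dsRNAi replicate 2 the adjusted p of OsMADS14 was 0.236, 0.0693 and 0.0967. Its call also ended with the series matrix (-0.13, adjusted p = 0.35), the deposited log ratio (0.105), offset 10 (0.0908), an intensity trend (0.069), antisense arrays averaged (0.114), both pairs averaged (0.611) and median centring (0.898). The adjusted p of OsMADS18 was 0.194 without antisense replicate 2, 0.0685 without dsRNAi replicate 2, 0.0852 with the deposited log ratio, 0.614 with both pairs averaged and 0.742 with median centring.

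The main comparison asked which genes differ in panicles that carry the RFL constructs, as the mean of both. The largest fall among cDNAs with a described product was in pyruvate decarboxylase 1 (AK100678), which makes acetaldehyde in alcoholic fermentation, at -7.17 ± 0.13 (adjusted p = 3.78e-07). A further pyruvate decarboxylase (AK100501, -4.14 ± 0.11, adjusted p = 4.01e-07) and glutamate decarboxylase (AK071556, -4.66 ± 0.13, adjusted p = 4.32e-07) also fell. So did cDNAs described as a salicylic acid carboxyl methyltransferase (AK070415, -5.92 ± 0.08, adjusted p = 8.25e-08) and an oxidase of 1-aminocyclopropane-1-carboxylate (AK102472, -5.18 ± 0.09, adjusted p = 3.16e-07), the last enzyme of ethylene synthesis. The largest rises were in a pair of cysteine proteinase cDNAs, AK072235 at 5.60 ± 0.14 and AK071495 at 5.49 ± 0.14, with adjusted p of 4e-07 and 4.01e-07. Isocitrate lyase (AK063353), an enzyme of the glyoxylate cycle, rose by 5.24 ± 0.16 (adjusted p = 5.57e-07).

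Other cDNAs among the 10 largest rises were described as the metallothionein OsMT-1 (AK103162, 4.81 ± 0.09), the germin-like protein GER2 (AK059781, 4.34 ± 0.14), a branched-chain amino acid transaminase (AK105963, 3.98 ± 0.14) and an O-methyltransferase (AK072740, 3.93 ± 0.18). Nuclease I (AK059608, 3.92 ± 0.11), an aminotransferase-like protein (AK100259, 3.86 ± 0.10) and a BURP domain protein (AK067523, 3.85 ± 0.12) completed them. The remaining 5 of the 10 largest falls were an I-box binding factor (AK107134, -4.75 ± 0.12), a peptide transporter (AK072119, -4.72 ± 0.12), the DNA-binding protein ABF2 (AK106282, -4.66 ± 0.12), the early nodulin OsENOD93a (AK105832, -4.49 ± 0.09) and a fatty acid elongase (AK067907, -4.26 ± 0.09). All 20 had the same sign on all 4 arrays. Wild type RNA was well above background on 2 of 4 arrays for AK059781 and AK072740, neither of them antisense, so background limits their values and places, and on 3 for AK063353, AK105963 and AK067523. Transgenic spots of AK072235 and AK071495 were saturated on 2 arrays, and wild type spots of AK100678, AK070415, AK071556 and AK105832 on 1.

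Of 17997 probes, 7508 passed an adjusted p of 0.05, of which 3682 rose and 3826 fell. Among them 633 rose and 832 fell by at least 2-fold, and 6199 had the same sign on all 4 arrays. Probes that passed in each construct on its own in the same direction numbered 1387 higher and 1549 lower than wild type. With each construct's arrays averaged into 1 value no probe passed in limma (3407 at an unadjusted p under 0.05), with construct as a random block 2594 passed, and with median centring in place of loess 1096 passed. The random block ended the calls of 18 of 68 named genes. Besides those given with their lists they were AK067523 (adjusted p = 0.0742), AK064401 (0.0872), AK107142 (0.0549), AK073365 (0.144), AK060265 (0.105), AK063624 (0.143), AK111500 (0.152), AK111996 (0.208), AK067214 (0.222), AK061051 (0.0967), AK102675 (0.24), AK064704 (0.442) and AK061899 (0.421). Some named genes called in the mean did not pass in each construct on its own. With dsRNAi these were AK111878 (adjusted p = 0.0819), AK073411 (0.334), AK060265 (0.284), AK067214 (0.694), AK063624 (0.343), AK111500 (0.12) and AK061051 (0.0596), and with antisense AK069103 (0.503), AK070894 (0.0549) and AK102675 (0.538), while AK111996 passed with neither (0.147 and 0.0989). Others are given with their values. The wild type channels also differed between the arrays of both constructs, as given with the difference between constructs.

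**Figure D1:**
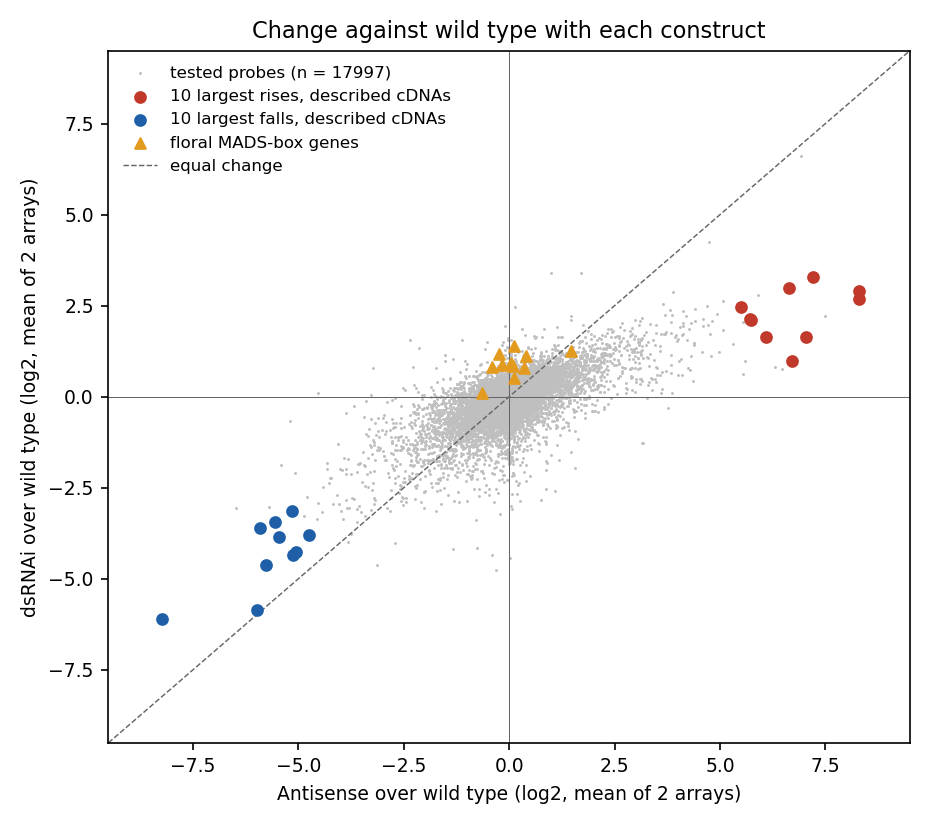
Mean log2 ratio of transgenic over wild type with the antisense construct (x axis) against that with the dsRNAi construct (y axis) for 17997 probes, n = 2 arrays per construct; colours mark the 10 largest rises and falls of described cDNAs and triangles the floral MADS-box genes. The largest rises lie below the dashed line of equal change, since their log ratios were smaller with dsRNAi.

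Floral organ and meristem genes of the MADS-box family, which specify spikelet and floral organ identity, were mostly higher than wild type. Adjusted over the list alone, 10 of the 11 measured members rose and 1 fell, and over all probes 8 rose and 1 fell. The members that passed adjusted over the list alone, 11 here, were 9 with the series matrix, 6 with the deposited log ratio and 1 with median centring. OsMADS5 (AK064184) rose by 1.36 ± 0.10 (adjusted p = 3.72e-05), OsMADS8 (AK072867) by 0.77 ± 0.08 (adjusted p = 0.000181), OsMADS6 (AK069103) by 0.75 ± 0.08 (adjusted p = 0.000212) and OsMADS2 (AK070894) by 0.57 ± 0.08 (adjusted p = 0.00112). With construct as a random block the adjusted p of OsMADS6 was 0.134 and that of OsMADS2 0.055. The member that fell was OsMADS14. The median of the list was 0.47 (camera adjusted p = 0.0109), and the adjusted p was 0.994 with an estimated correlation, 0.0525 with both pairs of arrays averaged and 0.0574 with construct as a random block.

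In the panicle branching and meristem list, 3 genes were measured, all of the KNOX homeobox family that maintains meristem cells. OSH15 (AK111877, described as HOS3) rose by 1.45 ± 0.09 (adjusted p = 9.24e-06) and OSH71 (AK111878, described as HOS9) by 0.83 ± 0.08 (adjusted p = 0.000129, and 0.0642 with construct as a random block). OSH43 (AK107296) stood at -0.18 ± 0.08 (adjusted p = 0.103). So 2 rose and none fell, both over all probes and adjusted over the list alone, and the list's median was 0.83 (camera adjusted p = 0.35). For the flowering time list, with 2 members measured, Hd3a and OsMADS56 (AK070135, 0.066 ± 0.08, adjusted p = 0.555), no member passed over all probes in limma or adjusted over the list alone. Its median was 0.076 (camera adjusted p = 0.851). A second OsMADS56 probe (AK062063) gave -0.55 ± 0.10 (adjusted p = 0.0029). Of 7 anther and pollen genes, included as markers of a later stage, 3 rose by either adjustment, over all probes and adjusted over the list alone, led by a pollen allergen homologue (AK070662, 1.48 ± 0.10, adjusted p = 2.19e-05). An anther-specific protein (AK064717) rose by 0.56 ± 0.09 and a second pollen allergen (AK067214) by 0.36 ± 0.09. The adjusted p of AK067214 was 0.0843 without antisense replicate 1. The median of this list was 0.24 (camera adjusted p = 0.35).

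**Figure D2:**
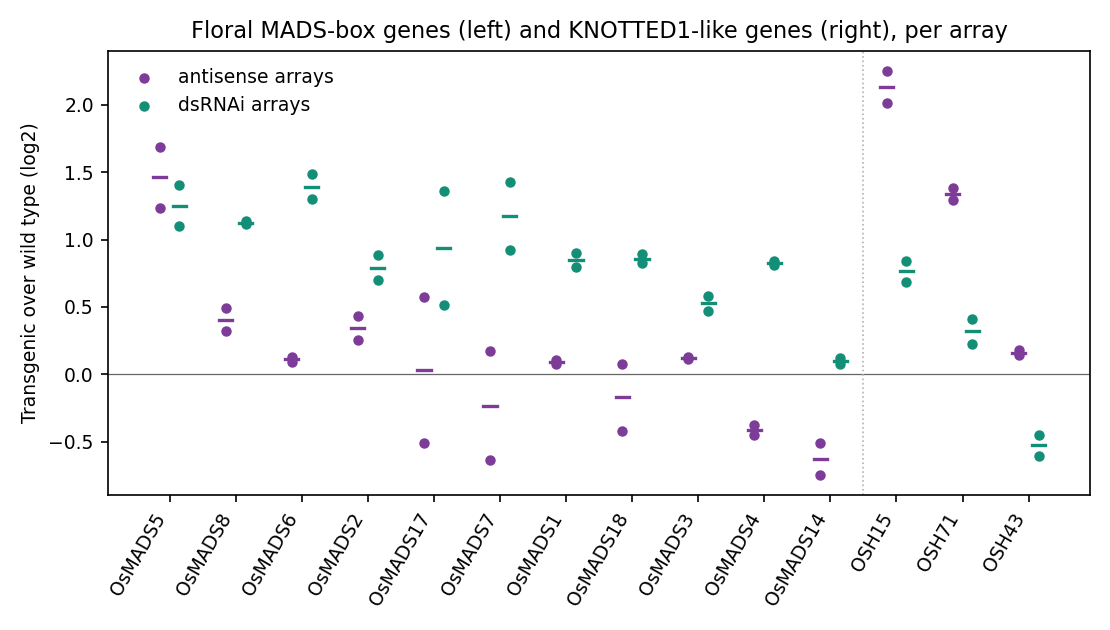
Log2 ratio of transgenic over wild type on each array (dots) with the mean of each construct (bars) for 11 floral MADS-box genes and the KNOX genes OSH15, OSH71 and OSH43. OsMADS5 lies near 1.36 with both constructs, while OSH15 averages 2.13 with antisense and 0.76 with dsRNAi.

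Hormone genes were measured as 3 lists found by description, in which cDNAs of the same gene count apart. Of 22 gibberellin genes, which act in growth through synthesis of and response to this hormone, 12 fell and 2 rose, over all probes and also adjusted over the list alone. A gibberellin 3-beta-hydroxylase (AK072410), which makes the active hormone, fell by 2.30 ± 0.09 (adjusted p = 1.92e-06). The chitin-inducible gibberellin-responsive genes CIGR1 (AK069266) and AK073470 fell by 1.76 ± 0.09 and 1.66 ± 0.12, and a gibberellin C-20 oxidase (AK107142) fell as well (adjusted p = 3.3e-05). The list's median was -0.31 (camera adjusted p = 0.07), and leaving out antisense replicate 1, antisense replicate 2 or dsRNAi replicate 1 gave adjusted p of 0.0397, 0.0202 and 0.0459. Of 64 auxin genes 12 rose and 16 fell over all probes, and 14 rose and 16 fell adjusted over the list alone. The auxin response genes IAA2 (AK073365) and IAA8 (AK109363) fell by 1.75 ± 0.11 and 1.53 ± 0.10. IAA2 fell by 3.39 with antisense and stood at -0.11 with dsRNAi (adjusted p = 0.692). Between constructs its wild type channels differed by -3.52 (limma separate channel adjusted p = 1.54e-06) and its transgenic channels by -0.24 (adjusted p = 0.605). The auxin list had a median of -0.027 (camera adjusted p = 0.851).

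Among 17 cytokinin genes, 5 fell and 3 rose, over all probes and adjusted over the list alone. A cytokinin oxidase (AK101022), of the family that degrades cytokinins, fell by 1.78 ± 0.08 (adjusted p = 2.55e-06), and cDNAs described as a cis-zeatin O-glucosyltransferase (AK111866), a cytokinin-regulated kinase (AK106429) and a cytokinin-binding protein (AK060655) fell by 1.52 ± 0.09, 1.39 ± 0.09 and 0.73 ± 0.08. For AK060655 the transgenic spot was saturated on 1 array and the wild type spot on 1, which limits its value. The cytokinin list's mean was -0.24 with a median of 0.000213, of opposite sign (camera adjusted p = 0.851). Limma's fry, which asks whether a list's members move one way without comparing them with other genes, gave an adjusted p of 0.0212 for gibberellin, 0.0212 for cytokinin, 0.0215 for panicle branching, 0.0296 for anther and pollen and 0.013 for floral MADS-box genes.

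Stress genes moved strongly in both directions. Of 169 heat shock and stress genes, 47 rose and 54 fell over all probes, and 48 rose and 55 fell adjusted over the list alone. Besides OsMT-1, metallothioneins AK058313 and AK062653, small metal-binding proteins, rose by 3.37 ± 0.10 and 3.07 ± 0.12, and a peroxidase (AK060007) by 2.90 ± 0.11 (adjusted p = 1.63e-06). Transgenic spots of AK058313 were saturated on 2 arrays, which limits its value. Secondary wall and lignin genes, markers of vascular tissue, included 14 that rose and 19 that fell of 57 over all probes, and 16 and 19 adjusted over the list alone. A cinnamoyl-CoA reductase (AK070746), an enzyme of lignin synthesis, fell by 2.70 ± 0.08 (adjusted p = 5.57e-07), and so did another (AK064401, -2.93 ± 0.13, adjusted p = 2.9e-06) and a phenylalanine ammonia-lyase (AK067801, -2.93 ± 0.14, adjusted p = 3.2e-06). A hydroxycinnamoyl/benzoyltransferase (AK070381) rose by 2.69 ± 0.11 (adjusted p = 2e-06). Transgenic RNA was well above background on 2 of 4 arrays for AK064401. The medians of the stress and wall lists were -0.030 and -0.040 (camera adjusted p = 0.851 each), with a fry adjusted p of 0.0435 for the wall list.

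Cell cycle and histone genes, 64 in number, had 11 that rose and 18 that fell over all probes, and 11 and 20 adjusted over the list alone. With median centring 0 of the 64 passed adjusted over the list alone. A histone H2A cDNA (AK064299) fell by 1.48 ± 0.08, while kinesins AK064200 and AK066227 rose by 0.99 ± 0.10 and 0.86 ± 0.08 and the replication factor MCM7 (AK073411) by 0.84 ± 0.11 (adjusted p = 0.116 with construct as a random block). Wild type RNA was well above background on 2 of 4 arrays for AK064200. Of 11 genes of the small RNA machinery, 2 rose and 2 fell by either adjustment, including adjusted over the list alone. An Argonaute cDNA (AK069685) fell by 1.54 ± 0.08 and OsAGO1 (AK111500) by 0.71 ± 0.17. HEN1 (AK111609), which methylates small RNAs, rose by 0.71 ± 0.09 and a second Argonaute (AK111996) by 0.29 ± 0.09 (adjusted p = 0.0309). Without antisense replicate 1, antisense replicate 2 or dsRNAi replicate 1, AK111996 stood at 0.29, 0.29 and 0.21 and was no longer called. Its call also ended with the deposited log ratio (adjusted p = 0.0993), an intensity trend (0.0594) and median centring (0.776). Among 27 ribosomal protein genes 1 rose (AK061051, 0.37 ± 0.08, adjusted p = 0.00827) and 2 fell over all probes, one of them AK102675 (-0.36 ± 0.10, adjusted p = 0.0203). Without antisense replicate 1, AK061051 stood at 0.32 and was no longer called. AK102675 stood at -0.26 without antisense replicate 2 and at -0.31 without dsRNAi replicate 1, and was called in neither. Its call also ended with the deposited log ratio (adjusted p = 0.0838), the series matrix (0.0888) and median centring (0.893). That of AK061051 ended with median centring (adjusted p = 0.744). Adjusted over the list alone limma called 0 of the 27.

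Photosynthesis genes, markers of leaf tissue, had 7 that rose and 11 that fell of 42, over all probes and adjusted over the list alone. With median centring 0 of the 42 passed adjusted over the list alone. A light-harvesting protein (AK061619) fell by 0.86 ± 0.20 (adjusted p = 0.0119), with -1.67 ± 0.29 in dsRNAi and no call in antisense (adjusted p = 0.929). Its level on the dsRNAi arrays was higher by 1.75 in the transgenic channels (limma separate channel adjusted p = 0.0184). In the wild type channels it was higher by 3.38 (adjusted p = 2.28e-05). Its call ended with the deposited log ratio (adjusted p = 0.0533), the series matrix (0.0529), the random block (0.284) and median centring (0.549). The 23 kDa photosystem II protein (AK065248) fell by 0.76 ± 0.10, a rubisco expression protein homologue (AK071896) fell by 1.02 ± 0.11, and Cab27 (AK060265) rose by 0.81 ± 0.08. Of 8 seed storage genes 2 fell over all probes and 1 adjusted over the list alone, a globulin-like protein (AK063624, -1.09 ± 0.19, adjusted p = 0.00288). The medians of the cell cycle, ribosomal, photosynthesis, seed storage and small RNA lists were 0.0015, 0.060, -0.012, -0.0035 and -0.045, with camera adjusted p of 0.851 for the first 4 and 0.947 for small RNA. The cell cycle list's mean (-0.034) and its test (downward) had the opposite sign to its median. No named strigolactone or tillering gene was measured (0 members). With an estimated correlation, no list fixed before the data were examined passed in camera in the mean of both constructs, with an adjusted p of 0.994 for each, and 0 of the 15 had an unadjusted p under 0.05.

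**Figure D3:**
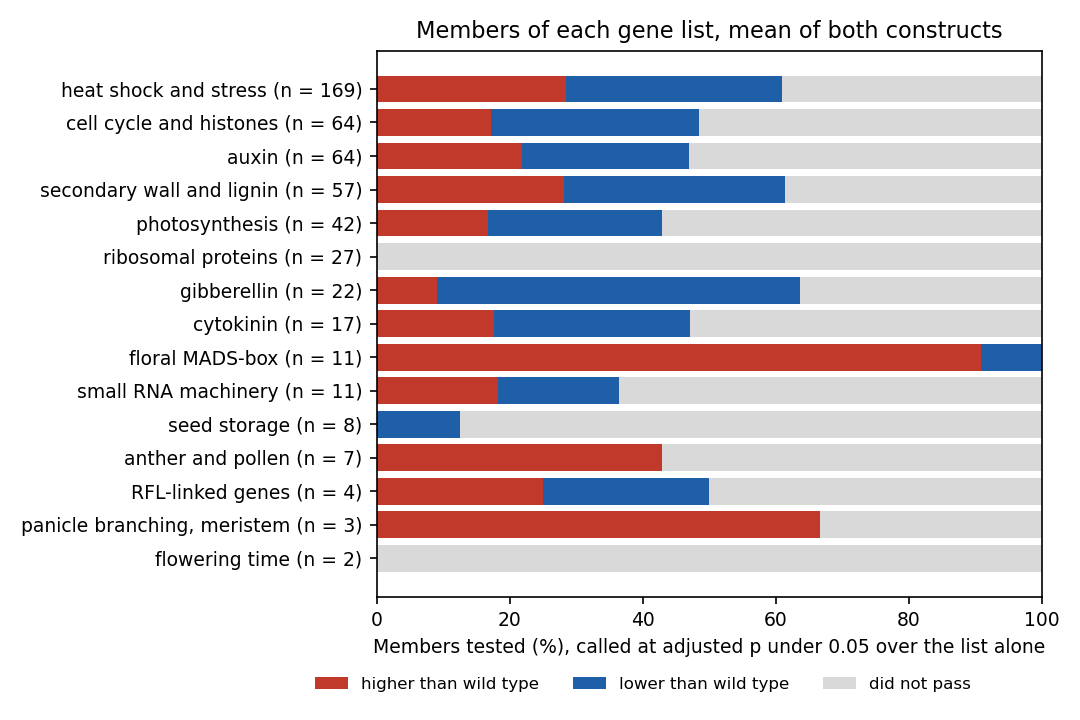
Percent of the measured members of each gene list that were higher than wild type, lower, or did not pass, in the mean of both constructs with p adjusted over the list alone. All 11 floral MADS-box genes passed, 10 of them higher, and none of the 27 ribosomal protein genes passed.

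With the antisense construct alone (n = 2 arrays), the cysteine proteinases AK072235 and AK071495 rose by 8.30 ± 0.19 and 8.29 ± 0.20 (adjusted p = 5.88e-07 each) and isocitrate lyase (AK063353) by 7.21 ± 0.22 (adjusted p = 1.08e-06). GER2 (AK059781), whose wild type RNA was not well above background on either antisense array, was at least 129-fold higher (adjusted p = 8.5e-07). BURP domain cDNA AK067523 rose by 6.70 ± 0.17 (adjusted p = 5.88e-07). The deepest falls were in pyruvate decarboxylase 1 (AK100678, -8.22 ± 0.19), the methyltransferase AK070415 (-5.98 ± 0.11), I-box binding factor AK107134 (-5.90 ± 0.16), AK102472 (-5.75 ± 0.13) and OsENOD93a (AK105832, -5.54 ± 0.13). Of 17997 probes 6693 passed, with 3397 higher and 3296 lower. Wild type RNA of AK063353 and AK067523 was well above background on 1 of the 2 arrays. Wild type spots of AK100678, AK070415 and AK105832 and transgenic spots of AK072235 and AK071495 were saturated on 1 of the 2, so these values and their order are limited by saturation. With median centring 837 probes passed.

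With the dsRNAi construct alone (n = 2 arrays), the largest rises were in a pair of cDNAs for PBZ1, a pathogenesis-related protein (AK071613, 3.41 ± 0.12, and AK099157, 3.40 ± 0.11, adjusted p = 1.01e-05 each). Isocitrate lyase (AK063353) rose by 3.28 ± 0.22, OsMT-1 (AK103162) by 2.98 ± 0.13 and cysteine proteinase AK072235 by 2.90 ± 0.19. Pyruvate decarboxylase 1 (AK100678, -6.11 ± 0.19), the methyltransferase AK070415 (-5.87 ± 0.11) and AK102472 (-4.61 ± 0.13) were among the deepest falls with this construct too. An isoflavone reductase-like cDNA (AK109339, -4.74 ± 0.20) and a jasmonate-induced protein homologue (AK066682, -4.34 ± 0.15, adjusted p = 1.01e-05) fell as well. Of 17997 probes 4639 passed, with 2017 higher and 2622 lower. Transgenic RNA of AK109339 was well above background on 1 of the 2 arrays. With median centring 186 probes passed, 59 higher and 127 lower.

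The difference between the constructs was tested as the log ratio with dsRNAi minus that with antisense. A dehydrin cDNA (AK063517), of a family of proteins made under water deficit, had a log ratio 4.64 ± 0.15 higher with dsRNAi (adjusted p = 4.06e-05), and a chitinase (AK065866) a difference of -5.72 ± 0.16 (adjusted p = 1.94e-05). Most of these differences lay in the wild type channels. Dehydrin stood at 9.82 and 9.86 (normalized log2 intensity) in the transgenic antisense and dsRNAi samples and at 14.35 and 9.75 in the wild type samples hybridised beside them. The chitinase stood at 15.07 and 14.76 in the transgenic and at 8.59 and 13.99 in the wild type samples. Its transgenic spot was saturated on 1 dsRNAi array, so the transgenic levels cannot be compared closely. OSH15 (AK111877) differed by 0.20 between the transgenic (adjusted p = 0.484) and by 1.57 between the wild type samples (adjusted p = 1.59e-05).

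Other differences above 0 were in a cinnamoyl-CoA reductase (AK064401, 4.54 ± 0.27), a cytochrome P450 (AK066760, 3.92 ± 0.16), an alpha-amylase (AK073487, 3.53 ± 0.23) and an OsENOD93a cDNA (AK059772, 3.42 ± 0.29). Transgenic RNA of AK064401 and AK059772 was well above background on 2 of 4 arrays. For AK059772 neither was a dsRNAi array and wild type RNA was well above background on 1 of the 2 dsRNAi arrays, so its difference and place are limited. The call of AK059772 ended with the deposited log ratio (adjusted p = 0.0842) and with median centring (adjusted p = 0.361). Differences below 0 were also largest in AK067523 (-5.72 ± 0.24), AK071495 (-5.60 ± 0.29), the Bowman-Birk inhibitor AK064050 (-5.47 ± 0.20) and AK059781 (-5.41 ± 0.28). Wild type RNA of AK059781 was not well above background on either antisense array, and transgenic spots of AK071495 were saturated on 1 array of each construct, so the size and order of these differences are limited. For the P450 the transgenic channels differed by 2.43 (limma separate channel adjusted p = 3.07e-05), more than the wild type channels at -1.49 (adjusted p = 4.71e-05). The PBZ1 cDNAs AK071613 and AK099157 were also higher in the dsRNAi transgenic channels, by 3.37 (adjusted p = 1.87e-06) and 4.03 (adjusted p = 3.32e-07), and in the wild type channels of the same arrays by 1.68 (adjusted p = 2.26e-05) and 1.61 (adjusted p = 1.95e-05).

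Floral MADS-box genes had higher log ratios with dsRNAi. Their median was 0.86 with dsRNAi (camera adjusted p = 2.44e-06, and adjusted p = 0.473 with an estimated correlation) and 0.089 with antisense (adjusted p = 0.884). The median difference was 0.76 (camera adjusted p = 4.36e-05, and adjusted p = 0.587 with an estimated correlation), with 7 members higher over all probes and 9 adjusted over the list alone, and 0 lower. With median centring 0 members differed adjusted over the list alone. The mean of the floral MADS-box genes differed by 0.32 between the transgenic and by -0.47 between the wild type channels. The KNOX genes of the panicle branching list differed the other way, with a median of -1.02 and all 3 lower both over all probes and adjusted over the list alone (camera adjusted p = 0.0134, and adjusted p = 0.635 with an estimated correlation). Here the wild type channels differed by 0.95 on average and the transgenic by -0.074. With median centring the camera adjusted p of the panicle branching list was 0.077.

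Heat shock and stress genes had a median difference of -0.13 (47 lower and 13 higher over all probes, 57 and 20 adjusted over the list alone, camera adjusted p = 0.0243, and adjusted p = 0.635 with an estimated correlation). Photosynthesis genes had a median of -0.25 (8 lower and 0 higher, over all probes and adjusted over the list alone, camera adjusted p = 0.0243, and adjusted p = 0.647 with an estimated correlation). For ribosomal protein genes it was -0.23 (4 lower over all probes, 3 adjusted over the list alone, camera adjusted p = 0.0243, and adjusted p = 0.672 with an estimated correlation). Photosynthesis genes were higher on the dsRNAi arrays in both kinds of sample, by 0.65 in the transgenic and 0.95 in the wild type channels. Their call ended with the deposited log ratio (adjusted p = 0.0965), the series matrix (0.0653) and median centring (0.204), and that of ribosomal proteins with median centring, where the median was -0.0035 (0.845).

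Over all probes 2962 of 17997 differed between the constructs, 1140 with a higher and 1822 with a lower log ratio with dsRNAi. In 2666 of them, or 90.0%, the wild type channels differed by more than the transgenic ones, with median sizes of 0.93 and 0.22. Fitted apart, the wild type channels of the dsRNAi and antisense arrays differed at 5818 probes (2960 higher, 2858 lower with dsRNAi) and the transgenic channels at 443 (239 higher, 204 lower). The correlation of levels across probes, which are not independent replicates, was 0.987 between the transgenic samples of both constructs and 0.946 between the wild type samples. Scan day and extraction software version coincided with construct, so a batch effect on the levels of either kind of sample cannot be told apart from construct, though one alike on both would cancel in the log ratio. This comparison of channels was chosen after the data were examined. With median centring 32 probes differed between constructs, 7 higher and 25 lower.

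The constructs were also compared for similarity across genes. Pyruvate decarboxylase 1, methyltransferase AK070415 and AK102472 were among the 5 deepest falls with either construct, and AK063353 and AK072235 among the 5 largest rises. The mean log ratios of antisense and dsRNAi had a Pearson correlation of 0.662 and a Spearman correlation of 0.556 across 17997 probes, and 68.4% had the same sign. Probes higher than wild type with both numbered 1387, against 381 for independent lists, and probes lower with both 1549, against 480. Another 177 were higher with antisense and lower with dsRNAi, and 74 the reverse. Arrays of one construct correlated at 0.933 (antisense) and 0.832 (dsRNAi), and arrays of different constructs at 0.596 to 0.641. In 20 simulations of unchanged groups, each control was shared by an antisense and a dsRNAi array. Their Pearson correlation was 0.502, the Spearman correlation 0.480, the same-sign share 66.7% and the covariance 0.00933, where the observed covariance was 0.297. On average 0.05 probes were called with both in one direction in the simulations. The simulations leave out the effects and the counts for independent lists the shared controls, so neither gives the size of a shared effect. In the separate channel fit the wild type channels differed between constructs at 5818 probes and the transgenic ones at 443. For those probes this argues against identical wild type RNA on the arrays of both constructs, which the simulations assume. The simulated 0.502 is thus from a setting unlike these data. The controls could not be split, so part of the excess may still come from wild type samples that were alike in part.

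The dye comparison set arrays with transgenic RNA in Cy5 against those with it in Cy3. No probe (0 of 17997), named or not, passed in limma with 1 residual degree of freedom, and 1860 had an unadjusted p under 0.05. The dye effect had an SD of 0.24 across probes, against 0.62 for the mean of both constructs. With median centring in place of loess, 13531 probes passed.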

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

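The tests of what lies in the wild type channels, of a shared wild type pool and of a later stage were chosen only after the result was seen. So were those of scan day and software version and of chance. The tests of normalization and of stretched antisense log ratios were written before they were run, but for patterns already read from these data. The count of probes, the lists fixed before the data were examined and the named cDNAs are here for a tested difference between the constructs' log ratios (dsRNAi minus antisense, limma adjusted p under 0.05). The fermentation and senescence lists were written after the largest changes were seen.

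Over all probes 2962 differed between the constructs. So did 5 of the 15 lists fixed before the data were examined, with median differences of 0.76 for floral MADS-box, -1.02 for panicle branching and meristem, -0.25 for photosynthesis, -0.23 for ribosomal protein and -0.13 for heat shock and stress genes. With an estimated correlation none of the 5 passed (lowest adjusted p 0.587), and with median centring panicle branching (0.077), photosynthesis (0.204) and ribosomal protein genes (0.845) did not, nor did photosynthesis genes with the deposited log ratio (0.0965) or the series matrix (0.0653). The sign of the arrays can be exchanged in 8 patterns, too few for a share under 0.05. The real pattern gave 7508 probes, and the highest of the others, 1 that exchanges both dsRNAi arrays and so tests the difference between constructs, gave 2962. As many as the real one came from 1 pattern, the real one.

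Of 78 named cDNAs 54 differed between the constructs, and 49 of them differed by more in the wild type than in the transgenic channels. Log ratios were higher with dsRNAi for 28, namely AK063517 (4.64), AK064401 (4.54), AK066760 (3.92), AK073487 (3.53), AK059772 (3.42), AK073365 (3.28), AK099157 (2.42), AK107134 (2.30), AK100678 (2.11), AK105832 (2.10), AK100501 (2.02), AK067801 (1.88), AK070746 (1.74), AK071613 (1.70), AK073470 (1.66), AK071556 (1.61), AK064299 (1.55), AK063624 (1.38), AK107142 (1.36), AK069103 (1.28), AK102472 (1.14), AK064704 (1.03), AK067907 (0.95), AK101022 (0.91), AK109363 (0.85), AK061899 (0.73), AK072867 (0.72) and 1 that is left unnamed (0.79). They were lower with dsRNAi for 26, namely AK067523 (-5.72), AK065866 (-5.72), AK071495 (-5.60), AK064050 (-5.47), AK059781 (-5.41), AK072235 (-5.39), AK100259 (-4.46), AK109339 (-4.43), AK066682 (-3.94), AK063353 (-3.93), AK103162 (-3.67), AK072740 (-3.63), AK059608 (-3.58), AK060007 (-3.36), AK105963 (-3.05), AK058313 (-2.45), AK062653 (-2.40), AK070381 (-1.96), AK061619 (-1.63), AK070662 (-1.53), AK111877 (-1.37), AK060265 (-1.24), AK073411 (-1.24), AK111878 (-1.02), AK106429 (-0.67) and another left unnamed (-1.05). For AK059781, AK072740, AK066682 and AK059772 a sample of 1 construct was near background on both its arrays, which limits their values. In 5 of the 54 the ratios of both constructs had opposite signs.

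Fermentation and low-oxygen cDNAs lay below wild type with both constructs. In the mean of both, 24 of 36 members were lower and 3 higher, with alcohol dehydrogenases 1 (AK069330) at -2.29 and 2 (AK102799) at -2.80. With antisense alone 20 were lower and 4 higher, and with dsRNAi alone 22 and 2. Array normalization as the cause is argued against by the list's highest adjusted camera p over 4 normalizations, 3.4e-06. A single wild type pool shared by both constructs, as the whole cause, is argued against by 25 members that differ between constructs after scaling, though with median centring, where 13531 probes held a dye effect, 0 of 36 did. Fitted apart, 9 members were higher and 17 lower in the wild type channels of the dsRNAi arrays, and 0 differed in the transgenic channels. So this test does not count against the state of the wild type samples as a cause of the fall. With an estimated correlation the adjusted camera p was 0.426, but that test also rests on few residual degrees of freedom. It therefore does not show whether a common factor moved these genes, which stays open. Growth or handling of the wild type panicles, a difference of stage and any lowering of RFL, whose level was not analysed, also stay open as untested. Low oxygen in tissue before freezing may raise such genes in wild type samples.

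In the mean of both constructs 26 senescence and remobilisation cDNAs were higher and 14 lower of 64 (median 0.12), and log ratios were higher with antisense, though with an estimated correlation neither the mean (adjusted p = 0.426) nor the difference (adjusted p = 0.146) passed. Their highest adjusted camera p over 4 normalizations was 9.87e-08 for the difference, and after scaling between arrays it was 4.79e-07, which argues against normalization and against antisense log ratios stretched as a whole. An additive effect of scan day or software version on 1 dye is argued against as the cause of the list's difference. It would change sign with dye orientation, and the smaller of the 2 mean differences was -0.887, with the same sign in the other. Other effects of scan day and software version coincide with construct and cannot be told apart from it. The wild type channels held 84.1% of the list's mean difference between constructs. Its standard error was 18.3% over the members, which are not independent replicates. A candidate explanation is thus that the wild type samples differed between the arrays of both constructs. A rise shared by both constructs may still follow from a lowering of RFL, whose level was not analysed. This was not tested apart from the state of the wild type samples.

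Floral MADS-box genes had higher log ratios with dsRNAi than with antisense, though with an estimated correlation the adjusted p was 0.587. Normalization is argued against by an adjusted camera p of at most 0.000922, though with median centring 0 of 11 members differed adjusted over the list alone. A stretch of the antisense ratios would place a list above wild type higher with antisense. The list's median was 0.089 with antisense and 0.86 with dsRNAi, which argues against it. The median difference after scaling was 0.793. Since scaling shrinks the antisense ratios, a difference of this sign was likely to stay, so that value adds little. An additive effect of scan day or software version on 1 dye is argued against too. The mean difference was 0.775 in the dye orientation where it was smaller, with the same sign in the other. Other effects of scan day and software version coincide with construct and cannot be told apart from it. The wild type channels held 59.8% of the mean difference with a standard error of 17.5% over the members, which are not independent replicates. Samples of both kinds may contribute, and the share does not settle it. A later stage of the dsRNAi panicles is not settled by anther and pollen genes, whose median difference was -0.0722 (camera adjusted p = 0.231), with 0 of 7 higher and 3 lower adjusted over the list alone and 1 lower over all probes, as their mean differed by 0.44 between the wild type and by 0.058 between the transgenic channels. A difference in how far each construct lowers RFL stays open too, as RFL's own level was not analysed here.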

How the results depend on the processing

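The alternatives were planned before the data were examined, except the 8 lists added later. Of the results for named genes, 1567 kept direction and side of the threshold, 133 no longer passed and 2 reversed, both of them not called: Hd3a (AK072979) at -0.030 without antisense replicate 2 (range -0.030 to 0.20 over arrays left out) and a gene left unnamed at 0.060 with median centring. For lists 434 held, 43 passed newly and 6 no longer passed. Median centring gave 1096 probes for the mean of both constructs, 837 for antisense, 186 (59 higher, 127 lower) for dsRNAi, 32 (7 higher, 25 lower) for their difference and 13531 for dye orientation. With both pairs averaged 0 probes passed in limma (3407 at unadjusted p under 0.05, lowest adjusted p 0.118), from fewer replicates. A random block for construct (correlation 0.413) gave 2594. At least 1 log2 unit on all 4 arrays held for 604 (229 higher, 375 lower). Leaving out 1 array gave 6251 to 7125, 4607 to 7317, 3118 to 5033 and 2499 to 2736 probes for the mean, antisense, dsRNAi and difference, with the lone array of a construct assumed to vary like the others.

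The correlation of the constructs was 0.642 with offset 10, 0.601 with the deposited ratio, 0.627 with the series table, 0.632 with median centring and 0.619 to 0.654 with an array left out. The gibberellin median was -0.69 with the series table (adjusted p = 0.0363), -0.37 with median centring (0.0276), -0.31 with antisense arrays averaged (0.0253), and -0.37 to -0.28 with an array left out. Floral MADS-box genes, at 0.47, had an adjusted p of 0.0525 with both pairs averaged, 0.0574 with the random block and 0.994 with an estimated correlation. Fry, whose question differs, passed gibberellin (-0.31), anther and pollen (0.24), cytokinin (0.000213), panicle branching (0.83) and secondary wall (-0.040). The cause was not tested for those without one given. No paired analysis was possible because the labels give no pairs, and the numbers share only dye orientation, which as a term gave 8143 probes for the mean and 3322 for the difference. Slide and scan date as a block were not run, since each array is its own slide and scan day coincides with construct. Signal over background limits wild type values of the largest rises.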

Other observations

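The lists in this part, and the tests on them, were chosen after the largest changes were seen, so they describe these arrays and are not independent evidence.

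Fermentation and low-oxygen genes fell together. Of 36 measured, 24 fell and 3 rose over all probes, and also adjusted over the list alone, with a median of -0.73 (camera adjusted p = 1.1e-06, and adjusted p = 0.426 with an estimated correlation). Besides the pyruvate decarboxylases, alcohol dehydrogenase 2 (AK102799) fell by 2.80 ± 0.11 and alcohol dehydrogenase 1 (AK069330) by 2.29 ± 0.10 (adjusted p = 1.92e-06 and 2.38e-06), which make ethanol, and a pyrophosphate-dependent phosphofructokinase (AK071798) fell by 3.80 ± 0.09 (adjusted p = 4e-07). Senescence and remobilisation genes rose more often than they fell, with 26 higher and 14 lower of 64 over all probes, 27 and 15 adjusted over the list alone, a median of 0.12 and a mean of 0.78 (camera adjusted p = 0.0107, and adjusted p = 0.426 with an estimated correlation and 0.0795 with both pairs of arrays averaged). A serine carboxypeptidase (AK073508) rose by 3.59 ± 0.08 and the aspartic protease homologue CND41 (AK072228) by 3.37 ± 0.08 (adjusted p = 4e-07 each).

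Ethylene genes included 2 oxidases of 1-aminocyclopropane-1-carboxylate that fell, AK102472 and AK058296 (-3.19 ± 0.08, adjusted p = 4.01e-07). Of 31, 5 rose and 11 fell over all probes, and 5 and 12 adjusted over the list alone (median -0.081, camera adjusted p = 0.0723). NAC transcription factors changed in both directions, with GRAB2 homologue AK073876 at 3.25 ± 0.09 and OsNAC4 (AK073848) at -3.25 ± 0.08. Of 32, 13 rose and 8 fell over all probes, and 13 and 9 adjusted over the list alone (median 0.15, camera adjusted p = 0.0698). In the KNOX list the class 2 gene HOS66 (AK060316) rose most, by 2.90 ± 0.11 (adjusted p = 1.73e-06), and 4 of 6 rose and 1 fell by either adjustment, including adjusted over the list alone (median 0.75, camera adjusted p = 0.061). Among 6 cDNAs of the FT and TFL1 family, 3 rose and 1 fell by either adjustment, including adjusted over the list alone, led by an FT homologue (AK106643, 0.82 ± 0.08, adjusted p = 0.000135; list median 0.22, camera adjusted p = 0.173). All cDNAs described as MADS-box genes had 13 of 29 higher and 5 lower over all probes, 14 and 5 adjusted over the list alone (median 0.21, camera adjusted p = 0.0577). Starch and sugar genes had 11 of 53 higher and 15 lower over all probes, 12 and 15 adjusted over the list alone (median -0.047, camera adjusted p = 0.195). An alpha-amylase (AK073487) fell by 3.63 ± 0.11 and the monosaccharide transporter OsMST3 (AK099079) rose by 1.81 ± 0.11.

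Several of these lists missed the threshold here and passed in other settings. The ethylene list passed with construct as a random block (adjusted p = 0.00139), antisense arrays averaged (0.0285), median centring (0.00708), fry (0.0104) and without antisense replicate 1 (0.0471), antisense replicate 2 (0.0186) or dsRNAi replicate 1 (0.0378). The KNOX list passed without any 1 array (adjusted p of 0.00552 and 0.0186 for the antisense and 0.0378 and 0.0384 for the dsRNAi replicates), with antisense arrays averaged (0.0117), median centring (0.00708), no filter on dim probes (0.0407) and fry (0.011). NAC genes passed with antisense arrays averaged (0.016), median centring (0.00708), fry (0.0104) and without antisense replicate 1 (0.0142), antisense replicate 2 (0.0186) or dsRNAi replicate 2 (0.0384). All MADS-box genes passed with antisense arrays averaged (0.0477), a dye term (0.0425), fry (0.0119), median centring (0.0372), no filter (0.0366), scaling (0.0499), the series table (0.0481) and without antisense replicate 1 (0.0471) or dsRNAi replicate 2 (0.0384). The FT and TFL1 family passed with fry (0.00197).

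Between the constructs, senescence genes had a median difference of -0.39 (camera adjusted p = 9.01e-08, and adjusted p = 0.146 with an estimated correlation), KNOX genes one of -0.85 (adjusted p = 0.00118, and 0.402), NAC genes one of -0.27 (adjusted p = 0.00482, and 0.395), all MADS-box genes one of 0.33 (adjusted p = 0.000839, and 0.395) and fermentation genes one of 0.25 (adjusted p = 0.0204, and 0.518, and 0.0909 with the deposited log ratio and 0.232 with the series table). The wild type channels of the dsRNAi arrays stood above those of the antisense arrays by 0.79 on average for senescence and 0.90 for KNOX genes, and for fermentation genes the value was -0.51. In the transgenic channels these means were -0.15, -0.19 and -0.11.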
